A study of Mus musculus with 2 samples.

How the data were processed

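The study sequenced RNA of sorted GFP-positive cells from the small intestine of C57BL/6 mice aged 6 to 8 weeks, with 1 library of Th17 cells from Il17a reporter knock-in mice and 1 of ILC3s from Il23r reporter knock-in mice. Groups were taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol and 1 ug entered the Illumina TruSeq RNA preparation. Per the submitters' processing notes, the tools were TopHat2 2.0.6, HTSeq 0.5.4p3 and DESeq 1.12.0, with genome build mm8. Their order and settings are not given in the sources used here. The number of animals per library is not given in the sources used here.

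The deposited table held 17048 rows. Its signal columns are the authors' size-factor-normalized counts for each library, headed as means although each group had 1 library. The authors also deposited a fold change, which equalled Th17 over ILC3 to a relative 1e-06 in 17048 rows, and a p-value and an adjusted p-value per gene. Those p-values come from 1 library per group and have no replicate behind them, and they are quoted only as the authors' deposited table. A repeat of the normalized counts in the last columns, filled in 896 rows, equalled the first and was not used. Names of 24 rows had been turned into calendar dates, as spreadsheets do to some gene symbols. They were left out of all comparisons and held 0.251% of the Th17 and 0.297% of the ILC3 reads, leaving 17024 genes.

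Whole reads were recovered from the normalized counts by dividing by the lowest value above 0 in each library, 1.18 for Th17 and 0.8504 for ILC3. All values (100% in both libraries) came out whole within 0.001 reads. The totals over listed genes were 17599180 and 22576436 reads. With 1 library per group no count model with replicates could be fitted. As an alternative on the recovered reads, the exact (Clopper-Pearson, conditional binomial) 95% interval of the ratio excluded equal values for 12296 of the 17024 genes, 6347 higher in Th17 and 5949 in ILC3. That number compares the reads of these libraries, not the cell types. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The floor for a gene listed at 0 was 3 reads per library, 3.53 normalized counts in Th17 and 2.55 in ILC3.

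The following choices were made before the data were examined. The difference per gene was log2(Th17/ILC3) of the authors' normalized counts with a pseudocount of 1, which understates the difference of low genes, while folds in the text are ratios of the normalized counts without it. A difference was called large at an absolute log2 ratio of at least 2 and at least 100 normalized counts in the higher library. No p-value was computed. For 26 gene lists, a member was measured at a mean of at least 10 normalized counts over both libraries. A list with at least 5 measured members was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size, matched in 20 bins of mean expression (seed 7). Genes within a list are not replicates, and the percentile describes these libraries. The lists hold 398 genes in 451 entries, and 51 genes are in more than 1 list; 27 entries had no row here and were not analysed. Medians with genes at 0 set to their bound are printed where they differ at 2 decimals.

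Named genes followed a rule. Il17a, Il17f, Il22, Il23r, Cd3e, Cd4, Kit, Il7r, Id2 and the sex-linked genes were always named. Added were the 10 largest ratios in each direction among genes with a large difference, the 5 most highly expressed of those in each library, and per list up to 4 members with a large difference and up to 2 without. Some genes that the rule would name are not reported here. Clone names, predicted genes, pseudogenes and immunoglobulin or T cell receptor segments were left out of the ranking. Gene names were matched to reference tables of assembly GRCm38.p6, another build than the authors', used for names and gene types only; 16965 of 17024 names were found, and no coordinates are given.

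The calculations were checked on simulated libraries with 200 of 17024 genes changed 8-fold. The size rule recovered 100% of them and took 0 unchanged genes, the interval held the true ratio for 95.7% of unchanged genes, and 7 of 100 lists of unchanged genes fell outside the central 95% of matched lists. These simulations hold counting error only. Alternatives were other scalings (total, median of ratios recomputed, upper quartile), pseudocounts of 0.1 and 10, other minimums and thresholds, and other matchings of the random lists. Added after seeing the data were a centring on constitutive gene families and an interval with ILC3 reads grouped by 10, the most frequent low read number of that library (from 4 reads up, smoothed over 5). Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.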

Results

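Transcripts were measured by RNA sequencing in T helper 17 (Th17) cells and in group 3 innate lymphoid cells (ILC3s) sorted from the small-intestinal lamina propria of C57BL/6 mice aged 6 to 8 weeks. Both populations respond to interleukin 23 (IL-23) and make type 3 cytokines, but ILC3s carry no antigen receptor. Th17 cells were T cells carrying GFP from an Il17a reporter knock-in, and ILC3s carried GFP from an Il23r reporter knock-in, so the mouse line, the reporter and the cell type differ together. Each group held 1 library, with 17599180 reads over all listed genes for Th17 and 22576436 for ILC3. No difference below therefore has a replicate check. Intervals are exact 95% intervals of the ratio for counting error only, and they compare these libraries, not the cell types.

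The comparison asks how the transcripts of intestinal Th17 cells and ILC3s differ. The Th17 library was higher for T cell receptor components, coinhibitory and costimulatory receptors, cell cycle genes, Il17a, Il17f, Ifng and Il10. The ILC3 library was higher for Il22, Csf2, Kit, Ncr1, Fcer1g, immediate early genes and markers of stroma and endothelium. A large difference was at least 4-fold on log2(normalized count + 1) with at least 100 normalized counts in the higher library. It was found for 668 genes higher in Th17 and 875 genes higher in ILC3, of 10431 genes that reached 100 in either library. The 875 include 11 of 13 measured stroma and endothelium markers, and the cells that these transcripts came from are not known. Centring on 146 genes of mitochondrial ribosomal proteins, proteasome and respiratory complex I, chosen after seeing the data, changed the split to 467 and 1188, since those genes were themselves 1.38-fold higher in Th17 at the median. At a 2-fold threshold in place of 4-fold the split was 1691 to 1673. In the authors' deposited table, 100 genes higher in Th17 and 206 higher in ILC3 had an adjusted p under 0.05, and all of them also had a large difference.

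**Figure D1:**
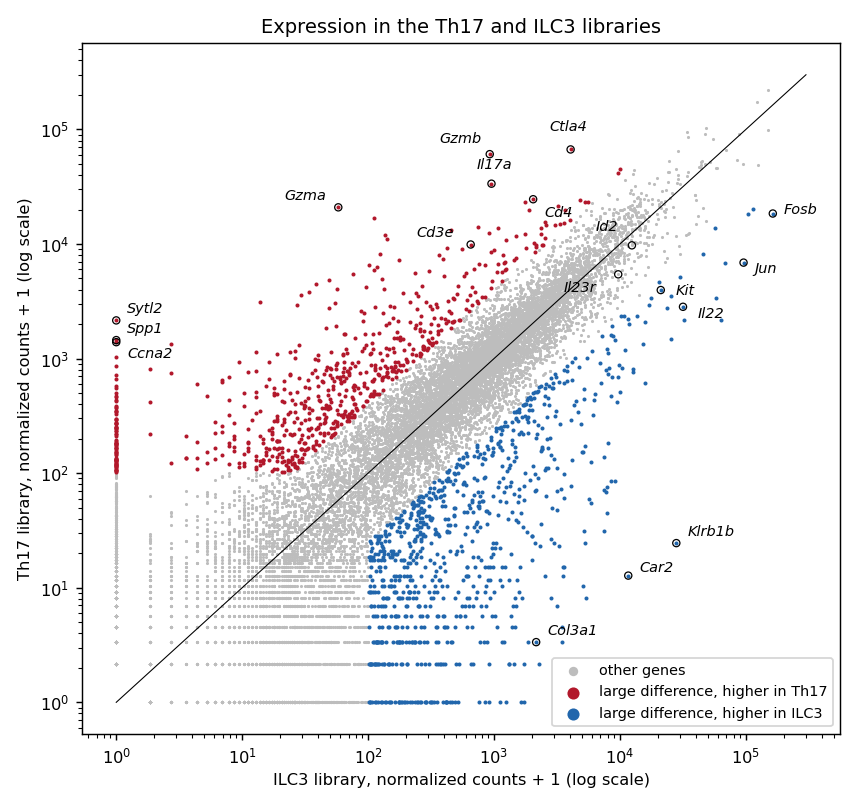
Each point is a gene, with its normalized counts plus 1 in the ILC3 library on the x axis and in the Th17 library on the y axis, both on log scales, and the line marks equal values. Red marks the 668 genes with a large difference higher in Th17 and blue the 875 higher in ILC3, with Il17a above the line and Il22 and Kit below it.

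The genes that carried the reporters were read first. Il17a, the cytokine gene whose reporter defined the Th17 sort, had 33614 normalized counts in Th17 and 953 in ILC3, a 35.3-fold difference (33.2 to 37.5). Il23r, the IL-23 receptor gene whose reporter defined the ILC3 sort, had 5435 in Th17 and 9688 in ILC3, 1.78-fold higher in ILC3 (1.72 to 1.84). The difference for Il17a is one the sort itself selects, and the ILC3 sort likewise selects for Il23r. In the authors' deposited table the adjusted p was 3.93e-04 for Il17a and 1 for Il23r.

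Among 18 measured genes of the type 3 program, 6 had a large difference higher in Th17, 3 higher in ILC3 and 9 had none. Il17f followed Il17a, at 23257 in Th17 and 1774 in ILC3 (13.1-fold, 12.5 to 13.7). Il21, a cytokine of helper T cells, had 810.2 normalized counts in Th17 and a single read in ILC3 (953-fold, 170.4 to 37683), and its receptor gene Il21r was 151-fold higher in Th17 (127 to 181). Ccl20, the ligand of CCR6, was 104-fold higher in Th17 (50.4 to 261). In the other direction, Il22, which acts on epithelium, had 2830.4 in Th17 and 31669.6 in ILC3 (11.2-fold, 10.7 to 11.7). Csf2, encoding GM-CSF, had 43.5 and 7959 (183-fold, 133 to 260.0). Maf and Stat3, transcription factors of the same program, were 2.86-fold and 2.05-fold higher in Th17, below the 4-fold threshold. The median log2(Th17/ILC3) of this list was 1.07, at percentile 99.98 of 10000 random lists matched on expression, over members that went both ways. In the authors' deposited table the adjusted p was 0.0194 for Il17f and 0.0325 for Il22.

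Cytokine and chemokine genes divided between the libraries, with 9 of 28 measured members higher in Th17, 7 higher in ILC3 and 12 without a large difference (median 1.72, percentile 100). Il10, encoding an anti-inflammatory cytokine, had 3121 normalized counts in Th17 and 12.8 in ILC3 (245-fold, 148 to 438). Tnfsf11, encoding RANKL, was 2.46-fold higher in ILC3 (2.38 to 2.54) and Tgfb1 2.41-fold higher in Th17 (2.32 to 2.501), both short of 4-fold. Ifng, named after its values were seen, had 19688 in Th17 and 1909 in ILC3 (10.3-fold, 9.87 to 10.8). Of 31 cytokine receptor genes, 3 had a large difference, all higher in Th17. These were Il21r, Il12rb2 (57.04-fold, 44.4 to 74.5) and the TNF receptor gene Tnfrsf1b (4.34-fold, 4.25 to 4.43). Il2rb and Ifngr1, the most highly expressed of the others by the mean of the 2 libraries, differed by 1.16-fold and 1.06-fold. The receptor list's median was 0.18 (percentile 48.9) and turned to -0.29 when centred on the constitutive families.

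T cell receptor complex and T lineage genes had 15 of 17 measured members with a large difference, all higher in Th17 (median 3.92, percentile 100). The Th17 group was defined as T cells and ILC3s carry no antigen receptor. The direction for receptor complex genes such as Cd3e therefore follows from the choice of groups. Cd3e, a signalling chain of the receptor complex, had 9897 normalized counts in Th17 and 651 in ILC3 (15.2-fold, 14.1 to 16.4). Cd4 had 24589 and 2044 (12.03-fold, 11.5 to 12.6). The 4 largest differences were for Ubash3a (127-fold), Cd6 (87.8-fold), Cd5 (66.2-fold) and Themis (57.6-fold). The exceptions were the kinase genes Lck, 2.92-fold higher in Th17 (2.82 to 3.01), and Zap70, at 8960.3 in Th17 and 9293 in ILC3. In the authors' deposited table the adjusted p was 0.0151 for Cd3e and 0.02599 for Cd4.

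Costimulatory and checkpoint receptor genes leaned the same way, with 15 of 19 higher in Th17, 1 higher in ILC3 and 3 without a large difference (median 4.04, percentile 100). Slamf1, Havcr2, Tnfrsf4 and Tigit were 119.7-, 115-, 112- and 103-fold higher in Th17. Ctla4, an inhibitory receptor gene and the most highly expressed gene with a large difference in the Th17 library, had 66883 in Th17 and 4056 in ILC3 (16.5-fold, 16.01 to 16.99), and Icos had 44897 and 10022 (4.48-fold, 4.39 to 4.57). Tnfrsf18 was 2.33-fold higher in Th17 and Cd226 3.57-fold higher in ILC3, both under 4-fold. Of 8 measured regulatory T cell genes, 7 were higher in Th17, 4 of them with a large difference. None had a large difference higher in ILC3 (median 2.22, percentile 100, or 1.22 at a minimum mean of 100 and 3.21 with no minimum). Foxp3, their lineage factor, was at 246 in Th17 and 16.2 in ILC3 (15.2-fold, 9.498 to 25.8), and Folr4 was 9.84-fold higher in Th17. Il2ra was 1.64-fold higher in Th17 and Ikzf2 2.46-fold higher in ILC3.

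Proliferation genes had 15 of 20 members with a large difference, all higher in Th17 (median 3.37, percentile 100). Ccna2, encoding cyclin A2, had 1389.9 normalized counts in Th17 and was listed at 0 in ILC3, at least 545-fold higher against a floor of 3 reads. Aurkb, Ccnb1 and Cdk1, which act in mitosis, were 177-fold (68.8 to 653), 74.8-fold (42.5 to 145) and 31.96-fold (21.8 to 48.9) higher in Th17. Pcna and Mcm6, which act in DNA replication, were 2.29-fold and 3.78-fold higher, short of 4-fold. Glycolysis genes had a median of 1.29 (percentile 100), with Pgk1 6.95-fold and Tpi1 5.06-fold higher in Th17 and the other 13 without a large difference, among them Pkm (2.45-fold higher in Th17) and Hk2 (2.56-fold higher in ILC3). Cholesterol synthesis genes had a median of 1.36 (percentile 100), with Fdps 6.35-fold and Sqle 4.896-fold higher in Th17. The remaining 14 had no large difference, among them Insig1 (2.39-fold higher in Th17). Interferon response genes had a median of 0.72 (percentile 99.57), with 11 of 18 higher in Th17. Of these, 2 had a large difference, Mx1 (13.4-fold, 7.99 to 24.02) and Gbp3 (4.37-fold). No member had a large difference higher in ILC3. Igtp was 1.59-fold higher in Th17. Reference genes were also higher in Th17 at the median (0.59, percentile 93.7), with B2m equal to within 1.003-fold, Actb 2.13-fold higher and Pgk1 the 1 member with a large difference.

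Genes of ILC3s and lymphoid tissue inducer cells had 10 of 19 members with a large difference, all higher in ILC3 (median -2.02, percentile 0). Ncr1, encoding the activating receptor NKp46, had 1725 normalized counts in ILC3 and 1 read in Th17 (1467-fold, 263 to 57959). Arg1, Fcer1g and Nrp1 were 537-fold (229.9 to 1655), 108-fold (81.1 to 148) and 67.1-fold (49.2 to 94.1) higher in ILC3. Nrp1 is also expressed by endothelium, whose marker Cdh5 was at 333 in ILC3 and listed at 0 in Th17. Kit, a stem cell factor receptor gene, had 3963 in Th17 and 21092 in ILC3 (5.32-fold, 5.13 to 5.52). Il7r was 3.69-fold higher in ILC3 (3.59 to 3.78) and Id2, encoding a factor required by innate lymphoid cells, 1.28-fold (1.24 to 1.31), so neither reached 4-fold. Centred on the constitutive families, Il7r passed that threshold, at -2.35 on the log2 scale. In the authors' deposited table the adjusted p was 0.368 for Kit, 0.909 for Il7r and 1 for Id2.

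Of 32 measured lineage transcription factor genes, 26 were short of a large difference (median 0.56, percentile 99.24). Of the rest, 4 were higher in Th17, including Irf4 (18.8-fold, 17.5 to 20.1), Foxp3 and Gfi1 (5.29-fold), and 2 were higher in ILC3. Ets1 and Ikzf3 were 2.15-fold and 3.38-fold higher in Th17. Chemokine receptor and adhesion genes had 7 of 25 higher in Th17, 4 higher in ILC3 and 14 without a large difference (median 1.00, percentile 99.99). Ccr4 and Ccr1 were 72.8-fold and 14.5-fold higher in Th17, whereas Cxcr5 was 59.8-fold higher in ILC3. Itgal and Cxcr6 were 2.14-fold and 1.78-fold higher in Th17.

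NK and cytotoxicity genes went both ways. Of 14 measured members, 5 had a large difference higher in Th17 and 6 a large difference higher in ILC3. Counting differences of any size, 8 were higher in Th17 and 6 in ILC3. The median (1.06, percentile 100) and the mean (-0.23) had unlike signs. Gzma and Gzmb, encoding granzymes, had 20896 and 60834 normalized counts in Th17 against 56.98 and 924 in ILC3 (367-fold, 289 to 473, and 65.9-fold, 62.02 to 70.01). Ncr1 and Fcer1g were the largest differences in the other direction, and Gzmc and Prf1 were 2.79-fold and 3.22-fold higher in Th17. Reads of similar granzyme genes may be split between them by the counting, so single granzyme values are uncertain. Of 10 measured ILC2 genes, 2 had a large difference higher in ILC3, Arg1 and Klrg1 (8.74-fold). Only Il9r had a large difference higher in Th17 (35.6-fold, 18.5 to 78.9). Their median was 1.32 (percentile 99.85), with Areg 3.41-fold higher in Th17 and Gata3 2.31-fold higher in ILC3. Of 10 listed genes of γδ and CD8 T cells, 6 were measured, with a median of -1.11 (percentile 7.55). Cd163l1 was 9.51-fold higher in ILC3, and Blk was at 755 in Th17 and 844 in ILC3. Most γδ receptor constant genes on that list had no row, so it says little about γδ T cells.

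**Figure D2:**
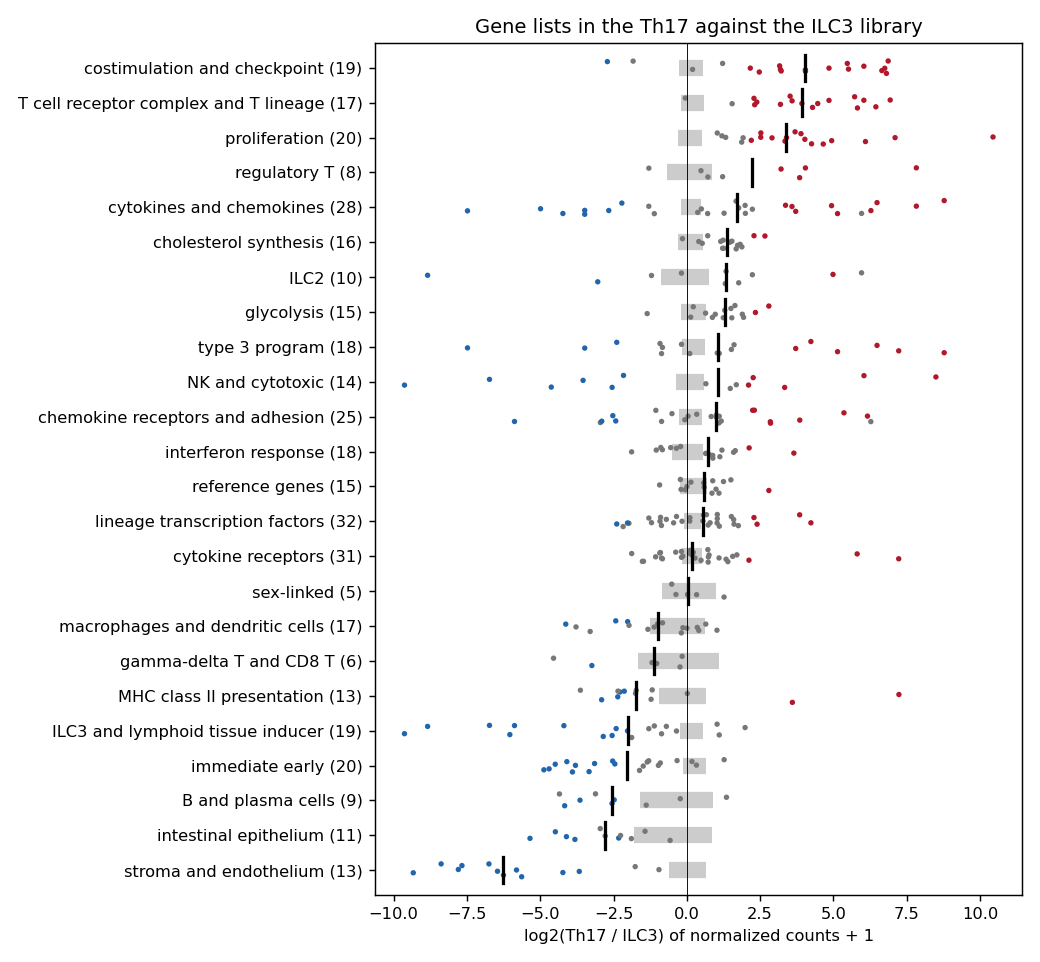
Each row is a gene list with its number of measured members in brackets, and each point is a member's log2(Th17/ILC3) of normalized counts plus 1, red or blue where the difference was large and grey otherwise. The black bar is the list's median and the grey band holds the central 95% of the medians of 10000 random lists matched on expression, with medians running from -6.26 for stroma and endothelium to 4.04 for costimulation and checkpoint.

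Immediate early genes, transcribed within minutes of stimulation or stress, were higher in ILC3. Of 20 members, 10 had a large difference and all of those were higher in ILC3 (median -2.04, percentile 0). The 20 genes together held 4.62% of the ILC3 reads and 0.971% of the Th17 reads. Zfp36 and Atf3 were 29.4-fold (28.1 to 30.8) and 17.1-fold (16.2 to 18.1) higher in ILC3. The heat shock genes Hspa1b and Hspa1a were 26.01-fold and 22.5-fold higher, but they are near-identical copies and the split of reads between them is uncertain. Fosb, Zfp36l1, Nr4a1, Jun and Fos were the most highly expressed genes with a large difference in the ILC3 library, at 163620.0, 112884, 104579, 95839.8 and 68429.9 normalized counts against 18449.7, 20392, 18098, 6879 and 6775 in Th17. Junb and Fosl2 were 2.55-fold and 1.26-fold higher in ILC3, under the threshold.

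Of 13 measured MHC class II presentation genes, 10 were higher in ILC3 and 3 in Th17 (median -1.75, percentile 0.12). A large difference was found for 4 of the 10 and 2 of the 3. Cd74, the invariant chain gene, was at 1166 in Th17 and 5980.1 in ILC3 (5.13-fold, 4.796 to 5.48), and H2-Oa was 7.83-fold higher in ILC3. Cd80 and Cd86, ligands of CD28 and CTLA-4, went the other way, Cd86 by 12.5-fold and Cd80 by at least 58.5-fold. H2-Ab1 and Ctss were 3.31-fold and 2.27-fold higher in ILC3. Markers of cells that make MHC class II moved in part with them. B and plasma cell genes had a median of -2.55 (percentile 0.53), with 8 of 9 higher in ILC3. Of these 8, 4 had a large difference, and no member had a large difference higher in Th17. Igj, the immunoglobulin J chain gene, had 10299 normalized counts in ILC3 and 822 in Th17, and Mzb1 was 20.04-fold, Cd79b 5.98-fold and Cd79a 5.83-fold higher in ILC3. Sdc1 was at 2354 in Th17 and 2754 in ILC3. Macrophage and dendritic cell genes had a median of -0.997 (percentile 6.78), which became -1.57 (percentile 1.57) at a minimum mean of 100, while without matching on expression the percentile was 0.56. Of their 17 measured members 3 had a large difference, Lyz1 (17.8-fold), Itgax (5.44-fold) and Lyz2 (4.11-fold), all higher in ILC3. Lyz1 and Lyz2 are close copies, and Csf1r and Xcr1 were 1.57-fold and 2.04-fold higher in Th17. C1qa, C1qb, C1qc and Cx3cr1 were at 91.7, 76.4, 58.8 and 54.1 in Th17 and at 68.9, 59.5, 67.2 and 59.5 in ILC3. Counting differences of any size, 12 of the 17 were higher in ILC3 and 5 in Th17.

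Markers of non-lymphoid tissue stood higher in the ILC3 library. Stroma and endothelium genes had 11 of 13 members with a large difference, all higher in ILC3, and a median of -6.26 (percentile 0; -5.97 with genes at 0 set to their bound). Col3a1, a collagen gene, was at 2159 normalized counts in ILC3 and 2.35 in Th17 (918-fold, 254 to 7585). Dcn was at 1401 and 5.88, and the endothelial genes Cdh5 and Kdr were listed at 0 in Th17 and at least 94.3-fold and 62.7-fold higher in ILC3. Pdgfrb and Pecam1 were 3.399-fold and 1.93-fold higher in ILC3. All 11 measured intestinal epithelium genes were higher in ILC3, 5 of them with a large difference (median -2.79, percentile 0.40). Their levels were low, such as 262 for Krt8, 184 for Olfm4, 179 for Muc2 and 158 for Krt19 in ILC3. Krt18 and Cdh1 were at 139 and 103 in ILC3 against 92.9 and 37.6 in Th17. Mast cell and granulocyte genes (3 measured, Cpa3 at 24.7 in ILC3 and 8.23 in Th17) and red blood cell genes (1 measured, Alas2 at 28.1 and 21.2) had too few measured members for a median.

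Sex-linked genes did not separate the libraries. Xist, transcribed from the inactive X chromosome, had 15292 normalized counts in Th17 and 15064 in ILC3, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 3122, 968, 424 and 976 in Th17 and 4468, 769.6, 550.2 and 405 in ILC3. Both libraries held RNA with Xist and RNA with Y-linked transcripts. The list's median was 0.02 (percentile 35.2), and it turned negative under scaling by the total (-0.09), by the upper quartile (-0.04) and on the constitutive families (-0.44).

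On log2 ratios with a pseudocount of 1, which lowers the rank of genes with few normalized counts, the largest in favour of Th17 were for Sytl2, Spp1, Ccna2, Cxcr1, Alpk2, Dnah8, Slfn1, Gzmg and Ccnf, all listed at 0 in ILC3, and for Sema4a. Sytl2, encoding a vesicle-trafficking protein, had 2153 normalized counts in Th17 (at least 844-fold), and Spp1, encoding osteopontin, 1449 (at least 568-fold). Sema4a had 1336 against 1.701 (785-fold, 217 to 6493). On the same scale, those in favour of ILC3 were for Tdrd9, Slc6a7, Arhgef28, Pcp4, Dscam and Gabbr2, listed at 0 in Th17, and for Klrb1b, Colgalt2, Slc6a20a and Car2. Klrb1b, an NK receptor family gene, had 28027 in ILC3 and 23.5 in Th17 (1192-fold, 772 to 1951), and Car2, a carbonic anhydrase gene, 11638 and 11.8 (989.7-fold, 538 to 2064). The authors' strand setting is not given in the sources used here, so reads of overlapping genes on opposite strands may not be told apart.

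Low read numbers were distributed unlike in the 2 libraries. In Th17, 2638 genes had 1 to 4 reads and 1049 had 8 to 15, whereas in ILC3 423 had 1 to 4 reads and 803 had 8 to 15. Genes listed at 0 numbered 714 in Th17 and 2237 in ILC3. A gene listed at 0 in ILC3 is not shown to be absent there. If each ILC3 molecule gave about 10 reads, a floor of 3 reads would lie below 1 molecule. The least folds given for genes at 0 in ILC3 would then be too high, and they were not recomputed for that case. Intervals of genes with few ILC3 reads, such as Aurkb (4 reads) and Ccl20 (7 reads), would be too narrow. With ILC3 reads grouped by 10, genes with an interval beyond 4-fold fell from 545 to 355 in Th17. In ILC3 they fell from 746 to 689.

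**Figure D3:**
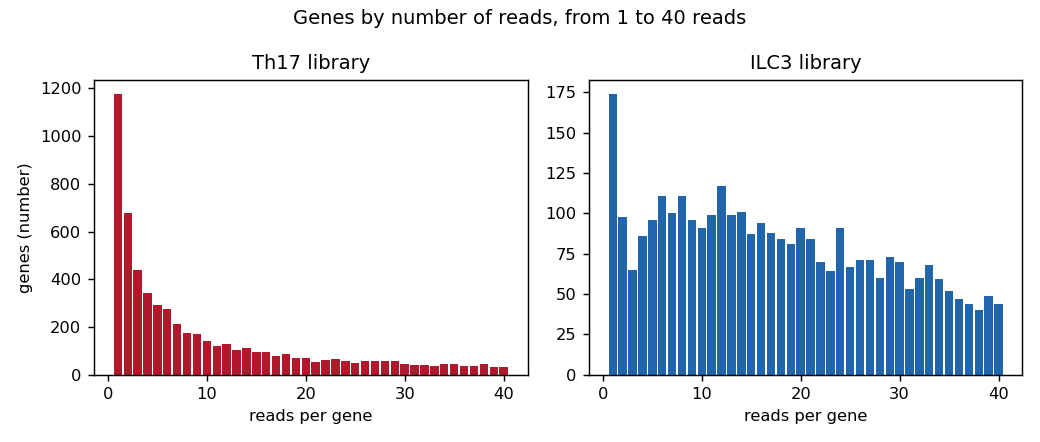
Bars give the number of genes (y axis) with each number of reads from 1 to 40 (x axis) in the Th17 library (left, red) and the ILC3 library (right, blue), on different y scales. The Th17 bars fall from 1178 genes with 1 read to 342 with 4, whereas in ILC3 174 genes had 1 read, 65 had 3 and more had 8 to 15 than 1 to 4.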

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

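The centring on constitutive gene families and the interval with grouped ILC3 reads were chosen after seeing the data. The numbers of genes with a large difference (668 higher in Th17, 875 in ILC3) stayed within 1.5 times under every scaling and pseudocount tried, from 467 to 672 and from 829 to 1188. They moved further with the thresholds, as fewer or more genes qualify. With no minimum they were 1923 and 2274, at a minimum of 500 normalized counts 343 and 408, and with the 2-fold threshold 1691 and 1673. A minimum of 20 gave 1733 in ILC3 and a log2 ratio of at least 3 gave 380 in Th17. Requiring the counting interval to lie beyond 4-fold gave 545 and 746; with ILC3 reads grouped by 10, the Th17 number was 355 and the ILC3 number 689. At an adjusted p under 0.01, the authors' deposited table held 58 genes higher in Th17 and 119 in ILC3.

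Scaling by the total shifted log2 ratios by -0.11, the upper quartile by -0.06, and the constitutive families by -0.46; the recomputed median of ratios shifted them by under 0.01. Of 237 list medians under alternatives, 2 moved beyond the 95% bootstrap range over list members, both on the constitutive families: cytokine receptors to -0.29 and cholesterol synthesis to 0.90. That range included 0 for the type 3, cytokine, cytokine receptor, lineage factor, chemokine receptor, NK, ILC2, interferon, macrophage and sex-linked lists. For those lists the percentile describes the median and not a shared direction of the members. Under other minimums or matchings, 3 percentiles, of macrophages and dendritic cells and of reference genes, left the central 95% of random lists; scalings shift all genes nearly alike and do not test percentiles. Of 60 values for 10 genes fixed in advance, 27 left their counting interval and 1 crossed the size rule. That was Il7r, at -2.35 on the constitutive families. No library could be left out, since each group had 1.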

Other observations

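The gene groups in this and the next paragraph were picked after their values were seen. Of 12 membrane receptor and channel genes, 8 had a large difference higher in ILC3 and 3 higher in Th17. Ret, the receptor gene of the GDNF family, was at 7462 normalized counts in ILC3 and 139 in Th17 (53.8-fold, 44.8 to 65.1), and Vipr2, encoding a receptor of vasoactive intestinal peptide, at 2573 and 62.3 (41.3-fold, 31.5 to 55.3). The channel genes Cacna1g and Kcnk1 were 299.8-fold (163 to 626) and 223-fold (144 to 365) higher in ILC3. Cx3cl1, Bmp2, Nos2, Dll1 and Hes1 were 542-, 790.1-, 413-, 391- and 237-fold higher in ILC3. Stroma and endothelium markers moved the same way (median -6.26), so the cells that these transcripts came from are not known. Spp1 and Mrpl47, picked in the same group as Cx3cl1, had 1449 and 165 normalized counts in Th17 and were listed at 0 in ILC3. Of the receptor genes, Cxcr1, Adora3 and Gpr174 had 1031, 337 and 754 normalized counts in Th17, the first 2 listed at 0 in ILC3 and Gpr174 at 1.701.

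Clock genes had 4 of 17 members with a large difference higher in ILC3 and 1 higher in Th17 (median -0.57). Nr1d1, Dbp and Npas2 were 15.7-fold (14.5 to 16.9), 10.995-fold (8.34 to 14.8) and 9.18-fold (7.28 to 11.7) higher in ILC3, Hlf was 7.68-fold higher in Th17 (7.18 to 8.22), and Arntl was 1.25-fold higher in ILC3. The time of day of each sort is not given in the sources used here. Hypoxia response genes went both ways (median 0.29, and -0.18 when centred on the constitutive families). Vegfa and Hilpda were 13.7-fold and 5.401-fold higher in ILC3, while Hif1a, Ndrg1 and Bnip3 were 6.63-fold, 6.86-fold and 4.66-fold higher in Th17. The metallothionein genes Mt1 and Mt2 were 14.2-fold and 4.88-fold higher in Th17, and Mt3 had 383 there and was listed at 0 in ILC3. Cytosolic ribosomal protein genes were 1.64-fold higher in Th17 at the median, with 74 of 77 higher there, and kept that sign under every scaling tried. Genes of mitochondrial ribosomal proteins (0.42 at the median on the log2 scale) and complex I (0.36) turned to -0.04 and -0.11 when centred on the constitutive families, which they belong to.

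In the 3 patterns weighed below, the tests on the second acinar, second stroma and second immediate early lists were written before their values were seen, and the others after. The first pattern is the shortage of genes with 1 to 4 reads in the ILC3 library. A minimum read count applied before deposit is excluded, since 337 genes were listed with 1 to 3 ILC3 reads. Among genes with at least 64 Th17 reads, 98 were at 0 and 13 at 1 to 4 reads in ILC3, a ratio of 7.54, while among genes with at least 64 ILC3 reads the ratio in Th17 was 0.387. Few starting molecules sequenced several times each stay open, since a molecule then gives several reads or none, but per the labels' protocols 1 ug of total RNA entered each preparation, which goes against few molecules at that step. Genes silent in ILC3 also stay open as a biological explanation. Only 1 of 145 constitutive genes with at least 64 Th17 reads was at 0 in ILC3 (Mrpl47), too few to decide. That count covers genes at 0, so it does not test why few genes had 1 to 4 reads.

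The second pattern is RNA of other tissues in sorted lymphocytes, which a GFP sort should remove. Digestive enzyme transcripts of the pancreas were found in both libraries, with Pnlip at 3819 normalized counts in ILC3 and 784 in Th17, Ctrb1 at 2958 and 608, and Cpa1 at 2522 and 467. A second list, with 6 measured acinar genes, had a median log2(Th17/ILC3) of -1.80, less than 1 from the -2.28 of the first 24 genes (SD 0.7498, picked after their values were seen), but within the central 95% of matched random lists (percentile 4.39) and with unlike ratios (SD 1.79, and Gm5409 1.24-fold higher in Th17), so RNA from acinar tissue in both libraries stays open. A second list of stroma, endothelium and muscle genes had a median log2(Th17/ILC3) of -4.56, with Eng at 1147 and Myh11 at 984 in ILC3, so RNA from such cells in the ILC3 library is a candidate source. The medians of the pancreatic and the first stroma list differed by 3.97 on the log2 scale, more than the larger SD of 2.4995. Unlike ratios go against 1 source of the same make-up in both libraries. The comparison was written after both medians were seen, so it does not decide on 1 common source of both. A source whose make-up differed between the libraries was not tested, nor was expression of these genes by ILC3s themselves.

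The third pattern is the higher level of immediate early genes in ILC3. The list's median stayed at -2.04 or lower under every scaling tried. All of these shifted log2 ratios downward, by -0.46 on the constitutive families, so they could not raise the median and do not decide on scaling. Against random lists matched on expression, the list's median was at percentile 0. A shift common to all genes would not change that position. A second list of 17 stress and immediate early genes had a median of -1.31, with Cebpd 15.1-fold and Dnajb1 3.87-fold higher in ILC3. Handling of the sorted cells before lysis and a difference between the cell types cannot be told apart here, because each cell type was prepared as 1 library from its own mouse line. Both stay open.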
